A study of Rattus norvegicus with 32 samples.

How the data were processed

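Hippocampal neurons of Sprague Dawley rats were taken at embryonic day 18 and cultured for 15 days, per the labels' protocols. Each of 16 single neurons, labelled pyramidal, gave 1 soma sample and 1 dendrite sample by aspiration with separate micropipettes. The neurons came from several cultures and days, and which neuron came from which culture or day was not given in the sources used here. Polyadenylated RNA was amplified by 3 rounds of antisense RNA amplification, a linear method based on in vitro transcription, and sequenced as stranded paired-end libraries, per the labels' protocols. No molecular identifiers are named there, so intervals on shares of counts cover counting error only. The amplified reads are not independent molecules.

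The authors deposited 1 table of whole-number counts per library, with 17308 rows: 17216 genes by symbol and 92 spike-in transcripts of the ERCC set, synthetic RNAs added to samples as a reference. The deposited counts were used as raw counts per gene, which their differing totals per library fit. Genome build rn6 is named in the submitters' processing notes. The aligner, the annotation, the handling of strand in counting and the treatment of reads that match several genes were not given in the sources used here. Counts of genes with near-identical copies, such as the tubulins and the ribosomal protein genes with their pseudogenes, are uncertain to that extent, as are those of overlapping genes. Spike-in rows stayed out of library sizes and of the tests of genes and gene lists, and entered only comparisons of spike-in totals per library. No coordinates are given, since no genome of that build was used here.

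Samples were grouped by compartment from the labels. The series text states that the soma and the dendrites with the same number come from 1 cell, so the neuron was a block in the main design. As a check of this pairing, the soma and dendrite profiles of 1 neuron, centred within compartments, had a mean Spearman correlation of 0.0678, against -0.00054 between neurons, and 4 of 16 neurons had a correlation over 0.1. The libraries of neurons 7 and 9 matched best across the 2 numbers, and the soma of neuron 8 matched the dendrites of neuron 9 best, so an exchange of labels among these neurons is not excluded, and paired values rest on the labels as given. Within either compartment, no 2 libraries agreed within sampling noise: the smallest chi-square per degree of freedom was 281 among soma pairs and 68.1 among dendrite pairs.

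Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passed filterByExpr by compartment (minimum count 10), which left 4916 genes holding between 91.8% and 97.2% of the gene counts of a library. After TMM normalization, dispersions were estimated with estimateDisp, and dendrites were tested against soma with glmQLFit (robust) and glmQLFTest. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes are log2 of dendrites over soma, and their SE is the absolute fold change over the square root of F. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at the estimated correlation, and with fry, from limma 3.58.1. A list score per neuron was the mean difference of log2 CPM (prior count 2) over tested members, dendrites minus soma.

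The lists comprised 22 gene lists and 8 sets of cell type markers. Of the 28 symbols sought for mitochondrially encoded genes, 0 were among the deposited gene rows, so that list says nothing about their level. The 13 microglia markers were among the rows, and 0 passed the filter. These lists thus had 0 tested members. The genes named were to be the 10 per direction with the smallest adjusted p under 0.05, an absolute log2 fold change of at least 1 and the same direction in at least 12 of 16 neurons. The rule added up to 4 members of each list with the smallest adjusted p, ties being broken by the unadjusted p, and 12 fixed genes. Of the fixed genes, Camk2a, Arc and Gfap did not pass the filter and are given as counts, and Malat1 and Meg3 were not analysed here. Some genes that the rule names are not reported here. The lists, the rule, the designs and most alternatives were fixed before the data were examined.

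To compare genes detected and similarity at 1 depth, counts were thinned at random to 1071293 gene counts per library, the smallest total among libraries with at least 1000000. Neuron 25, with both libraries under that minimum, was left out, leaving 15 neurons. Paired differences were tested with exact two-sided sign-flip permutation tests, whose smallest possible p with 16 neurons is 3.05e-05. Similarity was tested with 10000 two-sided permutations, swapping compartment labels within neurons or reassigning dendrites to neurons.

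Alternatives were a fit with no replicate block, DESeq2 size factors, library totals, no filter, a stricter filter (10 counts in 28 of 32 libraries), DESeq2 1.42.0 (Wald test with the block), limma-voom, a sign-flip test per gene, thinned counts, a non-robust fit and the omission of each neuron. Other count minimums, depths, correlations and gene numbers were tried for detection and similarity. Chosen after the data were examined were fits without neurons 20 and 25, without neurons 7 and 9 and without neurons 7, 8 and 9, a sign-flip test of the list scores, and detection and similarity without neuron 20, with the resemblance within neurons also tested without neurons 7 and 9 and without neurons 7, 8 and 9. The edgeR test was tested on simulated data for the 16 pairs with the 4916 genes: it recovered 4% of 100 genes changed 4-fold and 27% of 100 genes changed 16-fold, and called 0 of 4638 unchanged genes. The sign-flip test recovered 3% and 24% of the same genes and called 2 unchanged ones.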

Results

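Poly-A RNA was measured in the soma and in the dendrites of 16 single rat hippocampal neurons in culture, giving 16 soma and 16 dendrite libraries. Soma libraries held 14448584 ± 7076418 gene counts (SD, n = 16), between 878125 and 24721811. Dendrite libraries held 10292541 ± 8212642 (SD, n = 16), between 229149 and 24439768, and were the shallower library in 14 of 16 neurons (exact sign-flip permutation p = 0.0253, two-sided). The ratio of gene to spike-in counts did not differ detectably between compartments, with a mean difference of -0.06 in log2 (exact sign-flip permutation p = 0.858, 16 neurons).

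**Figure D1:**
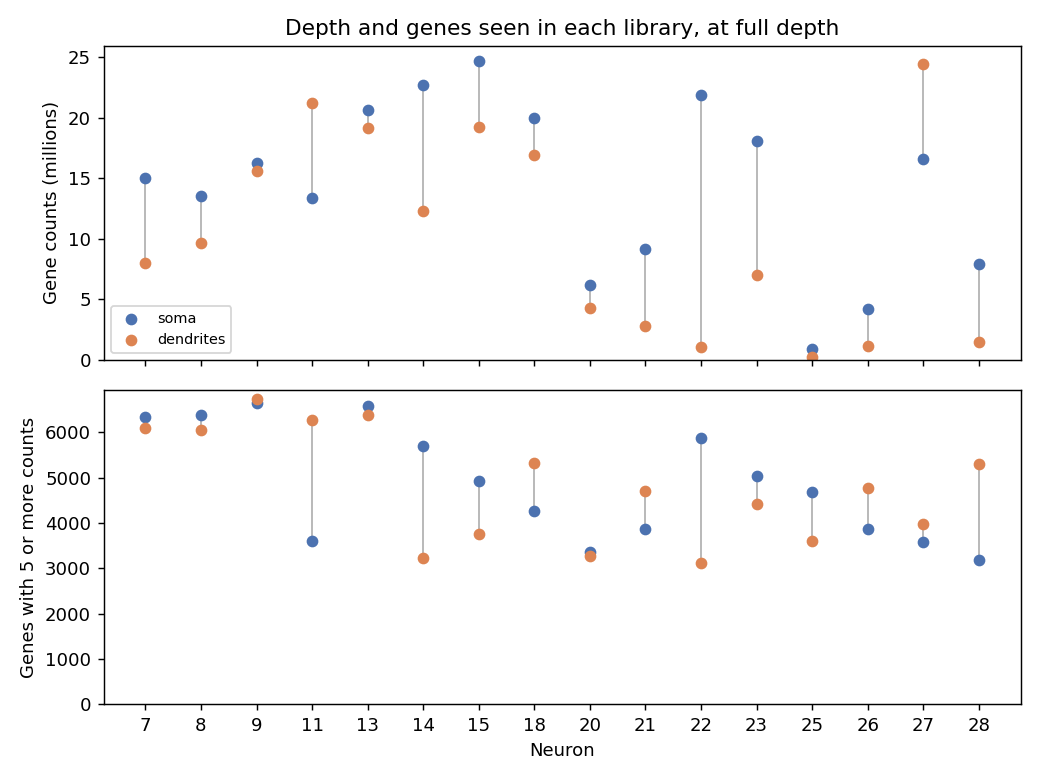
Gene counts per library in units of 1000000 (upper panel) and genes with 5 or more counts (lower panel) in each library at full depth, by neuron on the x axis; points are single libraries, blue for soma and orange for dendrites, and grey lines join the compartments of 1 neuron. Neuron 25 had both libraries under 1000000 gene counts.

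The most abundant transcripts were shared by both compartments: 17 of the 20 highest genes in soma were among the 20 highest in dendrites. Tuba1a, an alpha-tubulin of developing neurons, led both, with 55247 ± 35402 CPM in soma and 59028 ± 35915 CPM in dendrites (SD, n = 16). Tubb2b, a beta-tubulin, followed with 12160 ± 7432 CPM in soma and 16183 ± 15095 CPM in dendrites, then the imprinted neuronal gene Nnat with 9982 ± 12407 and 10994 ± 6140 CPM. Stmn2, which encodes a tubulin-binding protein, had 7533 ± 2666 CPM in soma and 8797 ± 2805 CPM in dendrites. Gap43, which encodes a growth cone protein, ranked 4 in soma with 7543 ± 3579 CPM and 8 in dendrites with 6210 ± 3061 CPM. These genes were picked by their level. Over the 4916 tested genes, mean CPM in soma and in dendrites had a Spearman correlation of 0.856 across genes, which are not independent replicates.

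The first comparison asked whether dendrites held fewer kinds of mRNA than the soma of the same cell. At 1071293 counts per library, 3978 ± 1088 genes had 5 or more counts in dendrites and 3850 ± 996 in soma (SD, n = 15 neurons). The mean difference, dendrites minus soma, was 129 ± 1294 genes, with more genes in dendrites in 7 of 15 neurons (exact sign-flip permutation p = 0.703, two-sided). Genes with 5 or more counts in every library of a compartment numbered 651 in dendrites and 624 in soma, and 443 had them in all libraries of both. In all, 10046 genes reached that count in 1 or more libraries. The difference was 502 genes at 1 or more counts and 201 without neuron 20, and turned at 20 or more counts, to -35.5 genes, and at full depth, to -53.5 genes, none past the threshold.

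The second comparison, of each neuron's dendrites with its own soma, asked which mRNAs differed in relative abundance between compartments. With edgeR's quasi-likelihood test, 0 of 4916 genes passed an adjusted p of 0.05. The median log2 fold change over all tested genes was 0.127. Unadjusted p-values under 0.05 numbered 129, against a median of 96 when compartment labels were swapped at random within neurons. Limma-voom and the sign-flip test per gene called 0 genes, and the DESeq2 Wald test called 404, of which 274 were higher in dendrites and 130 in soma. With compartment labels swapped at random within neurons, in fits of 1229 of the tested genes, DESeq2 called between 44 and 139 genes, with a median of 78, against 95 with the real labels. In data simulated at this depth and spread, the edgeR test recovered 27% of 16-fold changes, so most changes of that size were not detectable.

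Classical dendritic mRNAs, which encode proteins of synapses and dendrites known to be translated there, had 15 of 23 tested members higher and 8 lower in dendrites, with a median log2 fold change of 0.34 (camera adjusted p = 0.550), or 0.17 without neuron 20 and 0.22 without neuron 27. Nrgn, which encodes the calmodulin-binding protein neurogranin, had a log2 fold change of 3.62 ± 1.71 (SE, n = 16 neurons), and was higher in dendrites in 12 of 16 neurons. Shank1, a scaffold of the postsynaptic density, stood at 3.31 ± 2.03 and higher in 10 neurons, and Dlg4, which encodes the scaffold PSD-95, at 0.93 ± 0.58 and higher in 11. The dendritic microtubule protein gene Map2 was at 1.45 ± 1.62 (10 of 16 neurons), the postsynaptic gene Ddn at 0.87 ± 1.15 (9 of 16), the neurotrophin gene Bdnf at -0.86 ± 0.88 (higher in 6 of 16) and Actb, the cytoplasmic actin, at -0.05 ± 0.62 (8 of 16). Each of these genes had an adjusted p of 0.999 in edgeR's test. Nrgn reached 10 counts in only 8 soma and 10 dendrite libraries, with means of 15.9 ± 49.6 and 18.5 ± 27.9 CPM (SD, n = 16). Shank1 reached them in only 5 soma and 8 dendrite libraries, with means of 31.2 ± 88.0 and 11.4 ± 24.1 CPM (SD, n = 16). The mean of Shank1 was thus higher in soma, against the direction of its fold change. Camk2a, a kinase gene with mRNA known from dendrites, reached 10 counts in only 5 soma and 4 dendrite libraries, with means of 5.40 ± 15.1 and 7.79 ± 18.8 CPM (SD, n = 16). The immediate early gene Arc reached 10 counts in 5 soma and 6 dendrite libraries, with means of 13.1 and 13.5 CPM and highest libraries of 85.1 and 56.6 CPM. Postsynaptic density scaffolds had a median log2 fold change of 0.69 over 16 members and a mean of 0.34 (camera adjusted p = 0.754), with medians of 0.43 without neuron 20 and 0.40 without neuron 21. In the fit with no replicate block, Shank1 had a log2 fold change of -0.32.

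Cytosolic ribosomal protein genes stood higher in dendrites as a list: 71 of 78 tested members had a positive log2 fold change and 7 a negative one, with a median of 0.57 (camera adjusted p = 2.34e-05 at the preset correlation). The call was lost with an estimated correlation (adjusted p = 0.833, estimated correlation 0.413). Members with an adjusted p under 0.05 numbered 0 over all genes tested and 0 adjusted over the list alone. Rps16 was at 0.80 ± 0.34 (SE, n = 16), Rpsa at 1.17 ± 0.53 and Rpl13a at 0.88 ± 0.41, each higher in dendrites in 13 of 16 neurons (edgeR adjusted p = 0.999). The list score per neuron averaged 0.59 ± 1.33 log2 CPM (SD) and was positive in 13 of 16 neurons, with the highest value, 4.84, in neuron 20, without which it averaged 0.30 ± 0.71 (n = 15, exact sign-flip permutation p = 0.118). The camera call held in all 16 fits that each left out 1 neuron, with a highest adjusted p of 0.0304 and a median of 0.43 without neuron 20. It was lost without neurons 20 and 25, where the median was 0.37 (adjusted p = 0.185). The test fry, which asks whether the list changed at all and not whether it differed from other genes, gave an adjusted p of 0.454. With no replicate block the median was 1.65.

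Proteasome genes, which encode subunits of the main protein-degrading complex, stood lower in dendrites as a list, with a median log2 fold change of -0.27 and a mean of -0.51. Of 31 tested members, 19 were negative and 12 positive (camera adjusted p = 0.00104 at the preset correlation). The call was lost with an estimated correlation (adjusted p = 0.568). Psmc4, a base ATPase subunit, was at -2.67 ± 1.10 (SE) and higher in dendrites in 1 of 16 neurons, Psmd2 at -1.46 ± 0.72 and higher in 3, and Psmd6 at -2.46 ± 1.27 and higher in 5 (edgeR adjusted p = 0.999 each). Members past an adjusted p of 0.05 numbered 0 over all genes and 0 adjusted over the list alone. The score averaged -0.63 ± 1.18 log2 CPM (SD, n = 16) and was positive in 5 of 16 neurons. The call held in all 16 fits that each left out 1 neuron, while the median moved to -0.17 without neuron 14, -0.49 without neuron 18, -0.44 without neuron 20, -0.47 without neuron 22 and -0.45 without neuron 27. With no replicate block the median was -0.052 and the mean -0.048, and the call held. The adjusted p was 0.349 with fry and 0.121 with limma-voom, where the median was -0.05.

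**Figure D2:**
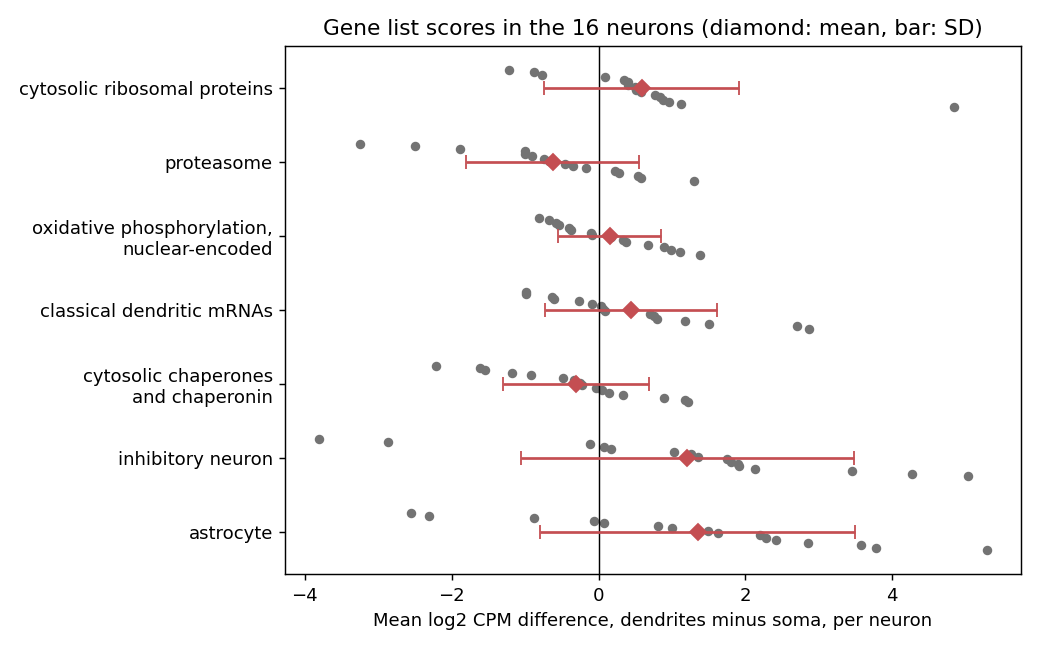
Score of 7 gene lists in each of the 16 neurons, as the mean difference in log2 CPM over tested members, dendrites minus soma; grey points are neurons, red diamonds the mean and bars the SD. The ribosomal score was positive in 13 of 16 neurons and reached 4.84 in neuron 20, and the proteasome score was positive in 5.

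Other lists did not pass at the preset correlation, and 0 lists passed with an estimated correlation or with fry. Cytosolic chaperones and chaperonin, which fold newly made proteins, had 15 of 20 members negative, a median of -0.34 and an adjusted p of 0.197, with Cct8 at -1.23 ± 0.78 (SE, n = 16). Nuclear-encoded oxidative phosphorylation genes had a median of 0.16 over 71 members (adjusted p = 0.860), near the median of 0.127 over all tested genes. Among them, Atp5i was at 1.07 ± 0.52 and Uqcrfs1 at -1.47 ± 0.76. Translation factors had an adjusted p of 0.794, and the cap-binding protein gene Eif4e and the helicase gene Eif4a2 stood at -2.42 ± 1.24 and -1.22 ± 0.65. The 3 tested long noncoding RNAs of the lists, Snhg11, Miat and Gas5, all had negative values, with a median of -2.15 and an adjusted p of 0.269, and Snhg11 was at -3.18 ± 2.14. RNA splicing genes had 28 of 43 members negative, a median of -0.15 and an adjusted p of 0.392, while U2af1 stood at 2.54 ± 1.19. Chromatin and transcription genes had an adjusted p of 0.794, with Hdac5 at 2.63 ± 1.48.

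Among membrane and cytoskeletal lists, GABA receptors had an adjusted p of 0.629, with Gabbr1, a subunit of the GABA-B receptor, at 1.37 ± 0.50 (SE) and higher in dendrites in 14 of 16 neurons. Glutamate receptors had 0.854, with Gria2 at -1.06 ± 0.82, and voltage-gated channels 0.794. Kinesin and dynein motors had 0.794, with the dynein intermediate chain gene Dync1i1 at -1.11 ± 0.45 and the dynein adaptor gene Bicd2 at 3.37 ± 1.59. Tubulins, microtubule proteins and neurofilaments had 0.980, with Tubb5 at 0.65 ± 0.36 and Map1b at 0.46 ± 0.26. Actin and spine cytoskeleton had 0.794, and synaptic vesicle and presynaptic release 0.874, with Nsf at -2.00 ± 1.35. The genes of ER translocation, folding and early secretion had 0.860, with 21 of 39 members negative, while Sec61a1 stood at 3.70 ± 1.98. Lysosome and endosome had 0.794, with Atp6ap1 at 1.31 ± 0.79, immediate early genes 0.980, with Ier5 at 3.62 ± 1.83, and glycolysis 0.641, with Tpi1 at -1.02 ± 0.79. The median and the mean differed in sign for GABA receptors, voltage-gated channels and motors. Camera's direction was down despite a median above 0 for translation factors, tubulins and lysosome genes. The medians of these last lists, 0.097, 0.117 and 0.039, lay below the 0.127 over all tested genes. The adjusted p of each gene named here was 0.999 in edgeR's test over all genes.

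Neurod6, a transcription factor gene of pyramidal neurons, had 10 or more counts in all 16 soma and all 16 dendrite libraries, with means of 1159 ± 1135 and 916 ± 898 CPM (SD, n = 16). The fewest, 22 counts, were in the dendrites of neuron 20, which resembled those of neuron 13, where Neurod6 had 5351. Slc17a7, the vesicular glutamate transporter gene, reached 10 counts in 5 soma and 2 dendrite libraries. As a list, pyramidal neuron markers had an adjusted p of 0.629, with Neurod2 at 3.87 ± 2.27 (SE). Inhibitory neuron markers had a median log2 fold change of 2.14 over 4 tested members (adjusted p = 0.237, and 0.568 with an estimated correlation), with Gad1, a GABA-synthesizing enzyme gene, at 2.36 ± 1.36 (edgeR adjusted p = 0.999). The median was -0.91 with no replicate block and -0.074 with limma-voom, where Gad1 stood at -1.41 and -0.60, and the list passed at the preset correlation without neuron 11 (median 2.56, adjusted p = 0.0480).

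Astrocyte markers had a median of 1.47 over 7 tested members, 6 of them positive, and a list score positive in 12 of 16 neurons (camera adjusted p = 0.197, and 0.568 with an estimated correlation). Apoe, a lipid carrier gene of astrocytes, was at 4.16 ± 1.55 (SE) and higher in dendrites in 13 of 16 neurons, and Mt3, a metallothionein gene, at 1.70 ± 1.19 and higher in 11 (edgeR adjusted p = 0.999 for both). Gfap, the astrocyte filament gene, reached 10 counts in 2 soma and 5 dendrite libraries, with means of 0.698 ± 2.24 and 15.0 ± 35.0 CPM (SD, n = 16). Endothelial, mural and fibroblast markers had a median of 2.01 over 2 members (adjusted p = 0.242), Dcn at 2.38 ± 1.40 and Sparc at 1.64 ± 1.38. Oligodendrocyte markers had 1 tested member, Cnp, at -1.92 ± 1.69 (adjusted p = 0.794), oligodendrocyte precursor markers 2, with Cspg5 at 0.90 ± 1.36 (adjusted p = 0.794), and dividing progenitor markers 1, Pcna, at -1.47 ± 1.45 (adjusted p = 0.603). The astrocyte median was 0.84 without neuron 7, 0.74 without neuron 21, 0.83 without neuron 25 and 0.86 with no replicate block, and at most 1.82, without neuron 15. The list passed in 6 of 16 fits that each left out 1 neuron (11, 14, 15, 18, 22 or 23), with adjusted p between 0.00252 and 0.532 over the 16, and passed without a filter on low counts (17 members, adjusted p = 6.34e-05).

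The third comparison asked whether dendrites varied more between cells than somata did, a question close to the series title, which speaks of drift at the level of cell compartments. Dendrite libraries of different neurons had a mean pairwise Spearman correlation of 0.436 ± 0.0594 (SD over 105 pairs of 15 neurons) and soma libraries of 0.412 ± 0.055. The difference, dendrites minus soma, was 0.0239 (permutation p = 0.288, two-sided, 10000 draws), so no difference in the spread between neurons was detectable. The most alike dendrite pair stood at 0.726, and at 0.558 without neuron 20. Over the 1000 highest genes the difference was -0.00605.

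The fourth comparison asked whether soma and dendrites of 1 cell resembled each other beyond their compartments' means. Centred profiles of the same neuron had a mean Spearman correlation of 0.0678 ± 0.0562 (SD, n = 16 neurons), and those of different neurons -0.00054 ± 0.058. The difference was 0.0684 (permutation p = 0.0001, two-sided, the smallest that 10000 draws can give). The permutation also separated libraries of 1 culture or day, and which neurons shared these was not given. Resemblance of a cell therefore cannot be told apart from that of its culture or day, or from RNA carried between its 2 libraries. The lowest neuron stood at -0.0542 and the highest at 0.193. The soma of 7 of 16 neurons matched its own dendrites best, as did the dendrites of 5 of 16 with their own soma. Neuron 9 was among the exceptions: the dendrites of neuron 9 matched the soma of neuron 7 best, with 0.259, and the soma of neuron 9 matched the dendrites of neuron 7 best, with 0.165, against 0.0699 within neuron 9. The soma of neuron 8 also matched the dendrites of neuron 9 better, with 0.231, than its own, with 0.193. Whether the libraries of neurons 7, 8 and 9 carry the right numbers is therefore open, and without these neurons the difference was 0.0578 (permutation p = 0.0001, 13 neurons). Libraries of these neurons also shared genes seen in few others, up to 93.9% from the dendrites of neuron 8 to those of neuron 7, as given under Other observations. An exchange of labels, a shared culture or day and RNA carried between libraries were not told apart.

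**Figure D3:**
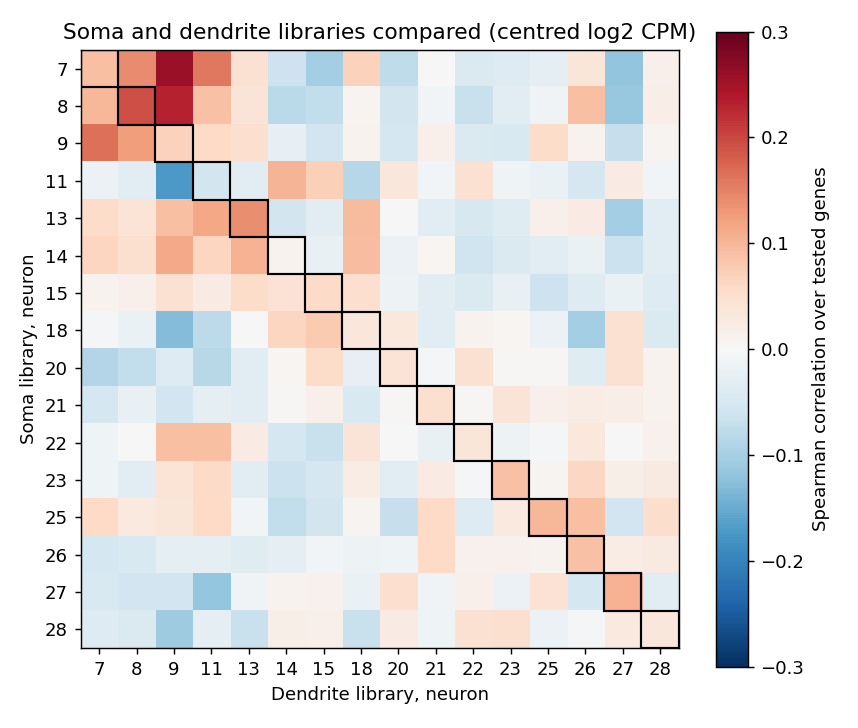
Spearman correlations between soma libraries (rows, by neuron) and dendrite libraries (columns, by neuron) over 4916 genes, in log2 CPM centred per gene within compartments; colours run from blue (negative) to red (positive) and boxes mark the same neuron. Boxed values averaged 0.0678 and the others -0.00054.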

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

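No control libraries without spike-ins were used here, so the ERCC spike-in counts, which entered the comparisons only through the ratio of gene to spike-in counts, were set against 0. They were present in all 32 libraries, with a median share of 0.482% of all counts. The lowest share was 0.0605%, in the soma of neuron 8 (95% exact binomial interval 0.0592% to 0.0618%). The highest was 4.33%, in the dendrites of neuron 20 (4.31% to 4.35%). The amount added to each tube was not given in the sources used here.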

How the results depend on the processing

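The fits without neurons 20 and 25, without neurons 7 and 9 and without neurons 7, 8 and 9, the sign-flip test of list scores and the omission of neuron 20 from detection and similarity were chosen after the data were examined. The count of 0 genes held in edgeR with other size factors, library totals, a stricter filter, thinned counts, a non-robust fit and no replicate block (336 genes at an unadjusted p under 0.05), in limma-voom, in the sign-flip test, without each neuron, and without neurons 7 and 9 (136 genes at an unadjusted p under 0.05) or 7, 8 and 9 (112), where both lists also passed. Without a filter 1 gene passed, higher in dendrites: Adam1a, named after its value was seen, with 33085 of its 38310 dendrite counts in neuron 20. DESeq2 called 404 genes, 274 higher in dendrites and 130 in soma. In 9 of 32 label assignments within neurons, the real one included, it called as many genes as with the real labels (95, highest other 139), so chance cannot be excluded; these fits used 1229 of the tested genes. With edgeR, all 100 assignments called as many genes as the real labels, which a real count of 0 fixes, and the highest other count was 0. Of the 100, 20 had as many genes at an unadjusted p under 0.05 (129, highest other 265).

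The number of lists passing, 2, was 4 without a filter, 1 with limma-voom, 1 without neurons 20 and 25, and 0 with an estimated correlation or by the sign-flip test. Without 1 neuron each, it lay between 2 and 4, with 4 without neuron 11. Of 100 assignments, 28 gave as many lists (2, highest other 8). The ribosomal median of 0.57 lost its call with an estimated correlation (adjusted p = 0.833), without neurons 20 and 25 (0.37, adjusted p = 0.185), and as a score of 0.59 in the sign-flip test (adjusted p = 0.330). The proteasome median of -0.27 lost its call with an estimated correlation (adjusted p = 0.568), with limma-voom (-0.053) and as a score of -0.63 in the sign-flip test (adjusted p = 0.330). The cause was not tested for these. Of 28 lists, 18 changed sign against their main median under 1 or more alternatives, the mean score of the sign-flip test counted among these. Medians changed sign for inhibitory neuron markers (-0.91 with no replicate block, -0.074 with limma-voom) and chaperones (0.070 with limma-voom).

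Of 41 named genes, 37 kept their direction throughout, and 16 passed with DESeq2 and 0 elsewhere. With no replicate block, Shank1 was at -0.32, Gad1 at -1.41 and Actb at 0.19. With limma-voom, Gad1 was at -0.60 and Cnp at 0.076. Actb was at 0.0042 with DESeq2 size factors, at 0.0035 with DESeq2, at 0.038 without neurons 7 and 9, at 0.019 without neurons 7, 8 and 9, and lay between -0.25 and 0.12 without 1 neuron each. The difference in genes detected was -35.5 at 20 or more counts and -53.5 at full depth, and that in similarity between neurons -0.00605 over the 1000 highest genes, none past the threshold. The resemblance within neurons passed under all of its alternatives, including the omission of neuron 20, between 0.0578 and 0.0997.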

Other observations

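The tests on neuron 20, on astrocyte markers found together in dendrites and in soma, and of scaling, depth and transcript type and the score relative to all genes for the ribosomal genes were chosen after the results were seen.

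Some libraries labelled pyramidal carried transcripts of GABA-releasing neurons at high levels. The soma of neuron 8 held Gad1 at 11161 CPM (95% Wilson interval 11105 to 11217) and the vesicular GABA transporter gene Slc32a1 at 817 CPM (802 to 832). Neurod6 stood at 61.8 CPM (57.8 to 66.1) in that library. In dendrites, Gad1 stood at 1833 CPM (1804 to 1863) in neuron 7, 1306 CPM (1289 to 1323) in neuron 18, 1069 CPM (1049 to 1090) in neuron 8 and 923 CPM (909 to 937) in neuron 15. Other markers in these dendrites did not all follow. Gad2, which encodes the other GABA-synthesizing enzyme, had 4 counts in neuron 7, 115 in neuron 8, and 0 in neurons 15 and 18, which allows up to 0.156 and 0.177 CPM (3 counts). Slc32a1 stood at 388, 469 and 286 CPM in neurons 7, 8 and 15, with 1 count in neuron 18. Neurod6 stood at 542 CPM (526 to 559), 337 CPM (326 to 349), 586 CPM (575 to 597) and 1123 CPM (1107 to 1139) in neurons 7, 8, 15 and 18. The soma of neuron 15 had 0 counts of Gad1, which allows up to 0.121 CPM. The interneuron peptide gene Sst stood at 858 CPM (844 to 872) in the soma of neuron 9 and at 689 CPM (671 to 707) in the dendrites of neuron 7. It was far lower in their partners, at 11.02 CPM (9.50 to 12.8) in the dendrites of neuron 9 and 10.3 CPM (8.83 to 12.1) in the soma of neuron 7. In neuron 8 it stood at 371 CPM (359 to 383) in dendrites and 36.6 CPM (33.5 to 40.0) in soma. Across compartments, the medians for Gad1 were 1.12 CPM in soma and 40.0 CPM in dendrites.

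The dendrite libraries of neurons 13 and 20 were the most alike of all libraries, with a Spearman correlation of 0.784 over 4916 genes at full depth, against 0.627 for the next pair. A candidate explanation is that reads or RNA of the dendrites of neuron 13 were carried into the other library. Of 164 genes with at least 1000 counts in the dendrites of neuron 13 and 20 or more counts in at most 8 further libraries, 100% had counts in the dendrites of neuron 20, at a median of 0.466% of the source count (quartiles 0.353% and 0.605%), while other libraries held 34.6% of them on average. For these 164 genes the narrow ratio argues against a shared cell type as the source of their counts. Even from the dendrites to the soma of neuron 13, the ratio over 170 such genes had quartiles of 0% and 15.4%. Whether neurons 13 and 20 also shared a cell type stays open: 29.7% of such genes of the soma of neuron 13 had counts in the soma of neuron 20, but libraries of 1 neuron also ranged from 21.1% to 83.6%, and 17 of 24 such pairs lay below the 95th percentile of 66.0% over 744 library pairs. The next highest pair was the soma of neurons 27 and 26, with 97.5% of 80 genes, at a median of 0.142% (quartiles 0.110% and 0.246%). This ratio was narrow as well, so a transfer from the soma of neuron 27 to that of neuron 26 is also a candidate, not tested further. Libraries of neurons 7, 8 and 9 followed. The dendrites of neuron 7 held 93.9% of 49 such genes of the dendrites of neuron 8, and 90.6% of 106 of the soma of neuron 8. The soma of neuron 8 held 90.1% of 151 such genes of the soma of neuron 9. In these pairs the ratio spread widely, with upper quartiles of 5.85%, 11.8% and 11.9%. If a transfer took place, whether it came before or during sequencing was not tested.

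More astrocyte markers were detected in dendrites: of 17, 7.40 ± 3.70 had 5 or more thinned counts in dendrites and 4.60 ± 2.03 in soma (SD, n = 15 neurons, higher in dendrites in 11, exact sign-flip permutation p = 0.0183, adjusted p = 0.0366 over the 2 marker sets tested). RNA of neighbouring cells taken up with the dendrites may account for this, but over all 91 markers of other types the mean excess of 5 did not pass (exact sign-flip permutation p = 0.0615), and a p above the threshold neither establishes nor excludes it. Of these 2 tests, only that over all other types was planned before the results were seen. Astrocytes were the only set tested alone, so the adjustment over 2 sets does not cover that choice. At full depth the astrocyte markers fell together in dendrite libraries more than in 98.79% of 10000 random lists matched on detection, and in soma libraries more than in 98.77%, with up to 13 of 17 markers in a dendrite library and 12 in a soma library, so arrival as a whole with dendrites alone is not shown. The most abundant were Aldoc, Sparcl1, Mt3, Fabp7 and S100b, with dendrite means of 120, 123, 112, 105 and 89.3 CPM against 63.1, 113, 46.9, 34.0 and 6.32 CPM in soma. Of the 17 markers, 4 had 10 or more counts in at least 12 of 16 soma libraries, 1 is also in the glycolysis list, and the labels name no sort that would remove astrocytes, so dendritic expression stays open.

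The higher ribosomal protein transcripts in dendrites were not set apart from chance: 20 of 100 assignments of labels within neurons, the real one included, gave this list a camera p as small (8.35e-07, smallest other 1.59e-23), and relative to all tested genes of the same neuron the score was 0.47 ± 1.94 (SD, 10 of 16 neurons, exact sign-flip permutation p = 0.346). The camera call was lost with an estimated correlation (adjusted p = 0.833), and without neuron 20 the median was 0.43, the preset call held (adjusted p = 0.0304) and the score did not pass (exact sign-flip permutation p = 0.118). Thinning to 1 depth did not shrink the shift: the median was 0.64 (camera adjusted p = 1.24e-07 at the preset correlation) and the score 0.68 ± 1.38 (SD, 15 neurons, exact sign-flip permutation p = 0.0374). Relative to all tested genes the thinned score was 0.57 ± 1.67 (10 of 15 neurons, p = 0.216 by the same test). The relative score did not pass at full depth either, so it does not bear on depth. Since the shift was not set apart from chance, depth was not excluded. The dendrites of neuron 20 had an extreme scaling factor (0.159). With library totals the shift was about as large, with a median of 0.58 (camera adjusted p = 3.22e-05 at the preset correlation) and a score of 0.54 ± 0.99 (SD, exact sign-flip permutation p = 0.0444, against 0.0589 with TMM). The relative score was 0.46 ± 1.86 (10 of 16 neurons, p = 0.334 by the same test). It did not pass with TMM either, so it does not bear on scaling, which for the same reason as depth was not excluded. Better recovery of short abundant transcripts stays open too: the ribosomal score exceeded that of oxidative phosphorylation genes by 0.44 ± 1.02 (SD, 12 of 16 neurons, exact sign-flip permutation p = 0.0896), and by 0.24 ± 0.64 without neuron 20 (11 of 15 neurons, p = 0.179 by the same permutation test).

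For the proteasome list, 1 of 100 assignments, the real one, gave a camera p as small (7.43e-05, smallest other 0.00182). That count takes no account of the 28 lists tested, and the call was lost with an estimated correlation (adjusted p = 0.568). A lower proteasome transcript level in dendrites is a hypothesis, with an exact sign-flip permutation p of 0.0479 for its score, or 0.330 adjusted over lists.

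A compartment difference shared by the neurons but too small for each gene was tested as a hypothesis. The squared length of the mean paired difference over all 4916 genes, at 1 depth, had an exact sign-flip permutation p of 0.282 (15 neurons). The mean correlation of paired differences between neurons was 0.0046. A p above the threshold does not exclude a smaller shared difference, and over the 1000 highest genes at full depth the exact p was 0.0715.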
